A study of Agrobacterium sp. CGMCC 11546 with 6 samples.

How the data were processed

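RNA was sequenced from 6 cultures of an Agrobacterium strain, a soil bacterium that makes the glucan curdlan, each sampled after 24 h of fermentation. The cultures were 3 of the wild type and 3 of a phbC deletion strain, described as biological repeats. Total RNA was extracted with Trizol and made into libraries with an Illumina TruSeq RNA kit, per the labels' protocols. Bowtie 0.12.2 and HTSeq are the tools named, per the submitters' processing notes. The reference genome and annotation, the alignment options, the treatment of strand and of ribosomal RNA, and any filter on reads are not given in the sources used here.

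The authors deposited 1 table per culture with RPKM values, reads divided by gene length and by the reads of the library, for 5457 gene identifiers. The same identifiers in the same order stood in all 6 tables. No scaling between libraries is stated beyond the division by the library total. The tables pair the identifiers with no gene name, product or position, and no reference annotation was used here. For that reason the 21 gene lists written before the data were examined were not tested. The phbC transcript was not looked up by name for the same reason. Genes are given by identifier, and at most 2 that rose and 2 that fell are named.

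The whole reads behind the RPKM values were recovered from their steps. A gene's RPKM is its reads times a factor set by the gene's length and the library's total, so the ratios of low values between libraries give the relative depth, and totals were taken as the smallest set that was whole in every library used. With those totals, 100% of the 4405 genes above 0 in all 6 libraries had a whole length between 30 and 20000 bases that gave whole reads in every library, within a tolerance of 0.01 read. When 3 of the totals were raised by 1%, 4.2% of the same genes did. The recovered lengths had a median of 849 bases and 98.9% were multiples of 3, so they are called coding lengths. The smallest length was taken where several gave whole reads, which may understate the reads of some genes. The recovered reads summed to between 99.75% and 99.82% of the totals, which were therefore taken as reads assigned to the listed genes. Totals were 7299497, 8075395 and 6451973 reads in wild-type replicates 1, 2 and 3, and 6918363, 6840010 and 7876959 reads in deletion replicates 1, 2 and 3. At the median length 1 read was worth between 0.146 and 0.183 RPKM, and a gene at 0 reads may have a level of up to 3 reads, between 0.438 and 0.548 RPKM. Such limits cover counting error only, since amplified reads without molecular identifiers are not independent molecules.

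Each library was divided by its median ratio to the gene-wise geometric mean, over genes above 0 in all 6 libraries. These factors were between 0.909 and 0.952 in 5 libraries and 1.415 in wild-type replicate 3. Genes with a mean of at least 1 RPKM over the 6 libraries were tested (4492 genes). Values were taken as log2(RPKM + 1) after scaling, so a fold change understates the change of weakly expressed genes. The strains were compared with limma 3.58.1 in R 4.3.3, a linear model per gene with moderated variances that follow the mean level, two-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Group levels are given as deposited RPKM, mean ± SD, n = 3. Genes to name were set by a rule, of which the parts that need gene names (phbC, list members and the neighbours of phbC) were not applied. The rest named those with the largest rise and fall past the threshold whose 3 and 3 deposited values did not overlap and whose mean was at least 10 RPKM, and the 5 with the highest mean RPKM. After the data were examined, genes in blocks of 1000 consecutive identifier numbers were also compared with all other tested genes by Fisher's exact test, two-sided, adjusted over 7 blocks.

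Pairs of libraries were compared on recovered reads by the chi-square per degree of freedom over genes with at least 20 reads. It was between 5.05 and 97.3 for replicates of a strain, where 1 is sampling noise, so no library repeated another. Replicates with the same number in both strains were checked for pairing through the correlation of their deviations from the strain means. It was 0.14, 0.17 and 0.30 for numbers 1, 2 and 3, which met the rule that every pair exceed 0.1. The rule does not show that the replicate numbers pair the samples. Deviations within a strain sum to 0, so the correlations are not independent of each other. Replicate 3 of each strain was above its other replicates in weakly expressed genes, by far less in the deletion strain. The 0.30 for number 3 therefore need not come from pairing. Deletion replicate 2 correlated with wild-type replicate 1 at 0.13. Deletion replicate 1 correlated slightly better with wild-type replicate 2, at 0.15, than with wild-type replicate 1. The labels name no shared day or batch. The model without the pairing remained the one reported, as fixed before the data were examined.

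The fit was tested on simulated data with 200 changed genes of at least 50 reads, drawn from the real gene levels and library totals. All genes had the same spread between replicates, a dispersion of 0.00219, which was a median over genes estimated without wild-type replicate 3. The shares found may therefore be too high for genes with more spread. Over 4335 tested genes without added background, 83.9% of genes changed 1.5-fold, 98.6% of those changed 2-fold and 100% of those changed 4-fold were found, and 0.12% of unchanged genes were called. With an uneven addition averaging 20 RPKM to wild-type replicate 3 alone (4535 tested genes), 38.2%, 87.5% and 89.7% were found and no unchanged gene of 4335 was called. With that library left out of the same simulation, 84.0%, 98.2% and 100% were found and 0.24% of unchanged genes were called.

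Alternatives fixed before the data were examined were the deposited scale, quantile normalization, pseudocounts of 0.1 and 10, no filter and a filter at 10 RPKM, a variance model without trend, the replicate block, a minimum size of change, and leaving out each library. Added after seeing the data were array weights, scaling on genes of at least 100 RPKM, removal of an even background of 16.4 RPKM from wild-type replicate 3, limma voom on the recovered reads, and 2 settings without wild-type replicate 3. Count-model tests had also been planned for the case that whole reads could be recovered. They were not run, because the deposited unit is RPKM, and voom was run on the recovered reads.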

Results

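The series compared the transcriptomes of a wild-type Agrobacterium strain and a strain without phbC after 24 h of curdlan fermentation. Curdlan is a beta-1,3-glucan that the bacterium secretes, and phbC is the usual name of a gene for poly-3-hydroxybutyrate synthase, which makes a storage polyester. The question, as the series title states it, was what part phbC has in making curdlan. Each strain was represented by 3 cultures and 1 library per culture, with between 6451973 and 8075395 reads on the listed genes. Of 5457 gene identifiers, 919 were at 0 in all 6 libraries, and 4492 were tested. The tables pair the identifiers with no gene name, so the level of phbC itself, which would check the labels, was not looked up by name.

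With all 6 libraries, 126 genes were higher and 86 were lower in the deletion strain (limma, adjusted p under 0.05), among 4492 tested. The genes that rose had a median log2 fold change of 0.92, with quartiles of 0.77 and 1.16. Those that fell had a median of -1.01, with quartiles of -1.47 and -0.82. An absolute log2 fold change of at least 1 was reached by 51 of the genes that rose and 43 of those that fell, and one of at least 2 by 10 and 6. After scaling, the values of the 3 deletion and 3 wild-type libraries did not overlap for 26.7% of tested genes, where chance gives 10%. In deposited RPKM the share was 32.5%, which includes any shift common to all genes. Without wild-type replicate 3, which stood apart from the other libraries, 553 genes were higher and 609 lower among 4346 tested. Their median log2 fold changes were 0.57 and -0.48, an absolute log2 fold change of at least 1 was reached by 100 and 72 of them, and one of at least 2 by 16 and 11. All 212 genes called with 6 libraries were among these, each in the same direction, and a further 950 were called. Without wild-type replicates 1 and 2 the counts were 123 and 113 genes, and without deletion replicates 1, 2 and 3 they were 73, 60 and 64. On the deposited scale, with no further scaling, 225 genes were higher and 384 lower with 6 libraries. There 36.9% of calls were higher, against 59.4% after scaling. The median log2 fold change of all tested genes was -0.25 on that scale and -0.055 after scaling. The share of calls that were higher depended on how wild-type replicate 3 was scaled. Its factor was 1.415 in the reported fit and 1.038 over genes of at least 100 RPKM. Dividing by 1.415 lowered its abundant genes and so raised their fold changes. Scaling on genes of at least 100 RPKM, chosen after seeing the data, gave 286 higher and 275 lower (51% higher). Without that library 47.6% of calls were higher.

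The largest rises were in Atu0485 and Atu0486, 2 identifiers with consecutive numbers and coding lengths of 354 and 1092 bases. Atu0485 went from 34.1 ± 4.97 RPKM in the wild type to 1584 ± 111 RPKM in the deletion strain (SD, n = 3 each), a log2 fold change of 5.70 with a standard error of 0.14 (limma, adjusted p = 3.9e-08). Atu0486 went from 79.1 ± 10.95 to 3311 ± 133 RPKM, a log2 fold change of 5.58 with a standard error of 0.15 (limma, adjusted p = 4.9e-08). In deposited RPKM these were ratios of means of 46.5 and 41.8. Each deletion library held between 3627 and 4378 reads of Atu0485, against 81 to 91 in each wild-type library. Without wild-type replicate 3, the log2 fold changes were 5.61 and 5.48.

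The largest falls were in Atu1604 and Atu2708. Atu1604, with a coding length of 1860 bases, had 241, 233 and 390 reads in wild-type replicates 1, 2 and 3, or 21.9 ± 9.23 RPKM (SD, n = 3). It had 0 reads in each of the 3 deletion libraries. Wild-type replicate 3 was highest, at 32.5 RPKM against 17.8 and 15.5 in replicates 1 and 2. With that value the mean over the 6 libraries was 10.96 RPKM, just above the 10 RPKM of the naming rule. A count of 0 over the 3 deletion libraries together allows a level of up to 0.0745 RPKM, so Atu1604 was at least 208-fold lower than in the lowest wild-type library. It passed the test in limma with an adjusted p of 0.0017, but not when genes under 10 RPKM were left out of the fit (adjusted p = 0.18). The fitted log2 fold change was -4.36 in both, and its standard error went from 0.51 to 1.81. Over the alternatives its adjusted p was between 3.8e-09 and 0.18. Atu2708, with a coding length of 1278 bases, fell by 3.42 on the log2 scale, with a standard error of 0.21 (limma, adjusted p = 3.6e-05). Its level was 569 ± 34.5 RPKM in the wild type and 45.4 ± 4.19 RPKM in the deletion strain, a ratio of means of 12.5. For each of these 4 genes an exact two-sided permutation test of the 6 values gave p = 0.10, the smallest that 3 against 3 allows.

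**Figure D1:**
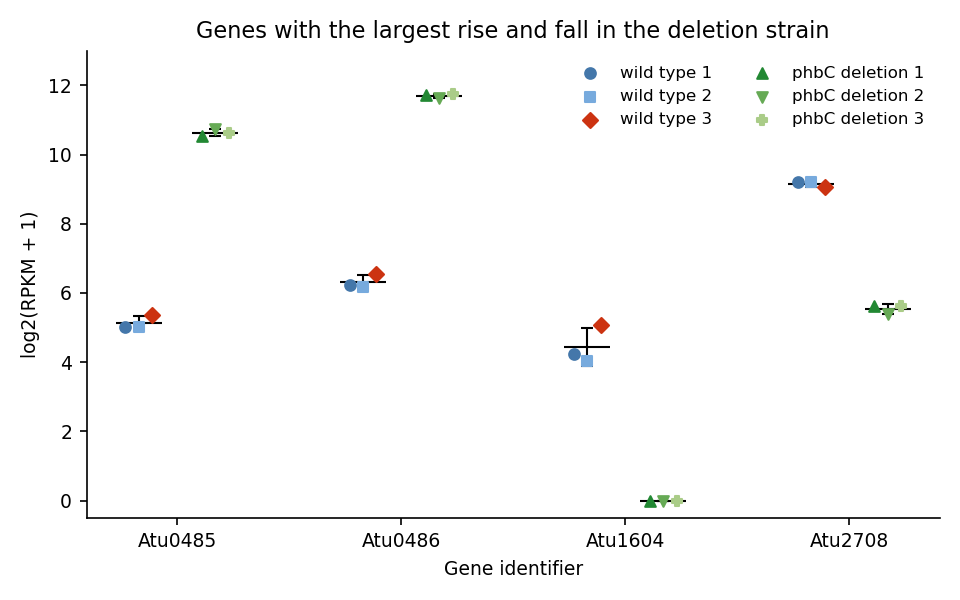
Levels of the 4 genes with the largest rise or fall. The vertical axis is log2(RPKM + 1) of the deposited values, each point is 1 library, and bars give the mean and SD of 3 libraries per strain. Atu0485 and Atu0486 were higher in every deletion library, Atu2708 was lower in every deletion library, and Atu1604 was at 0 in all 3.

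None of the 5 most abundant transcripts passed the test with 6 libraries. Atu2109 took 5.88 ± 2.26% of reads in the wild type and 8.34 ± 0.71% in the deletion strain (SD, n = 3), with 3.34% in wild-type replicate 3. Its log2 fold change of 0.79 had a standard error of 1.62 (limma, adjusted p = 0.83). That standard error depended on the variance model. At the same fold change it was 0.49 without the trend and 0.40 with the filter at 10 RPKM (limma, adjusted p = 0.53 and 0.29). The fold change was 0.21 without wild-type replicate 3, with a standard error of 0.18 (limma, adjusted p = 0.45), and between 0.21 and 1.13 over the alternatives other than quantile normalization, which sets the most abundant gene to 1 value in all 6 libraries. Atu1468 followed, with 5.85 ± 0.42% of reads in the wild type and 7.41 ± 0.28% in the deletion strain (limma, adjusted p = 0.80). Its standard error likewise went from 0.91 to 0.25 without the trend (limma, adjusted p = 0.40). Atu3752 stood at 29288 ± 5898 and 40604 ± 2967 RPKM (limma, adjusted p = 0.68), Atu1020 at 28238 ± 1532 and 24290 ± 1356 RPKM (limma, adjusted p = 0.99), and Atu1131 at 17733 ± 2484 and 17636 ± 1466 RPKM (limma, adjusted p = 0.87). Without wild-type replicate 3 the log2 fold changes of Atu1468, Atu3752 and Atu1020 were 0.27, 0.31 and -0.27. Their standard errors were then 0.13, 0.11 and 0.11 (limma, adjusted p = 0.17, 0.078 and 0.12). Atu1131 was at -0.13 (limma, adjusted p = 0.43). The deposited values of Atu1468, Atu3752 and Atu1020 did not overlap between the strains, as in 32.5% of tested genes. A missed threshold therefore does not show that they were unchanged. For Atu1020 and Atu1131 the sign of the fold change depended on the libraries or the scaling used. Together these 5 genes took between 13.1% and 20.5% of the reads of a library.

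Calls were found at most levels of expression. With 6 libraries, 1 gene rose and 1 fell among 912 genes under 10 RPKM, 77 rose and 57 fell among 2287 genes at 10 to 100 RPKM, 45 rose and 25 fell among 1081 genes at 100 to 1000 RPKM, and 3 rose and 3 fell among 212 genes over 1000 RPKM. Without wild-type replicate 3, the counts were 49 and 17 under 10 RPKM, 288 and 250 at 10 to 100, 187 and 291 at 100 to 1000, and 29 and 51 over 1000. The median standard error of a log2 fold change was 0.22 with 6 libraries and 0.12 without that library.

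**Figure D2:**
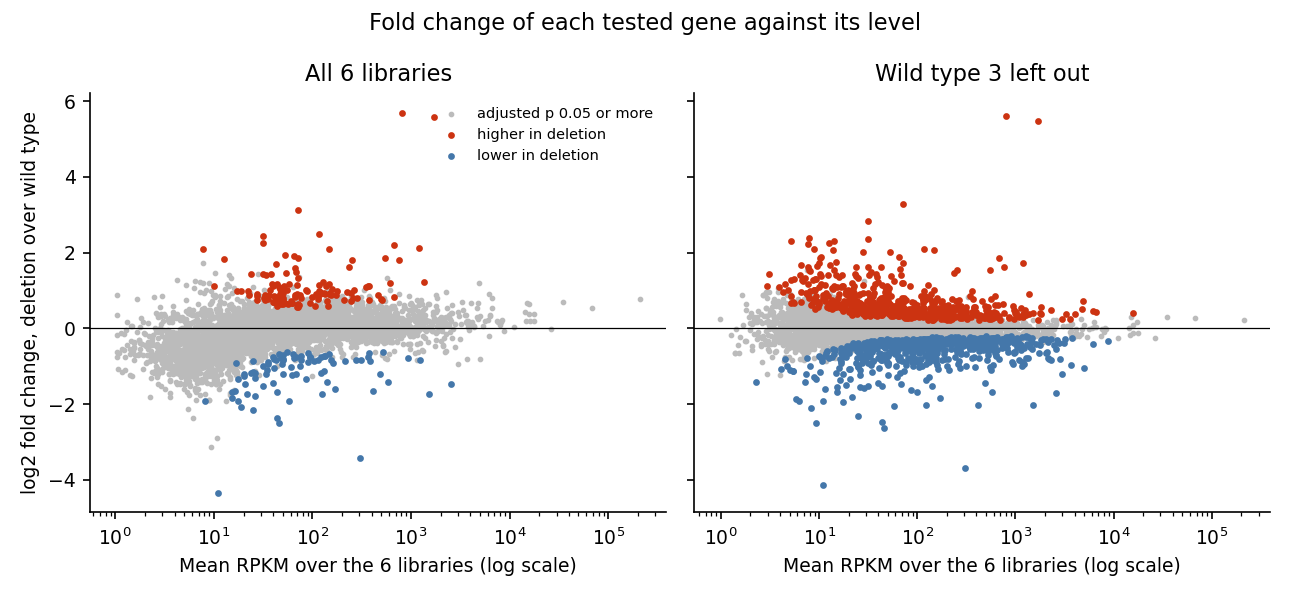
Fold change of each tested gene against its level. The horizontal axis is the mean RPKM over the 6 libraries on a log scale, the vertical axis is the log2 fold change of the deletion strain over the wild type, and colours mark genes with an adjusted p under 0.05 in limma. Left, all 6 libraries (126 higher, 86 lower); right, wild-type replicate 3 left out (553 higher, 609 lower).

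Wild-type replicate 3 differed from the other 5 libraries at both ends of the range of levels. Among 205 genes with a mean of 1 to 2 RPKM in the other libraries, its median was 19.1 RPKM, against 1.30 and 1.34 RPKM in wild-type replicates 1 and 2 and 1.41 to 1.88 RPKM in the deletion libraries. Among 397 genes at 300 to 1000 RPKM its median was 508 RPKM, against 502 and 510 RPKM in the other wild-type libraries. Among 56 genes over 3000 RPKM its median was 4574 RPKM, against 5488 and 5549 RPKM in the other wild-type libraries and 5241 to 5588 RPKM in the deletion libraries. Over tested genes, its log2 values correlated with those of wild-type replicates 1 and 2 at r = 0.927 in both cases, across genes, which are not independent replicates. Replicates 1 and 2 correlated with each other at 0.994, and the deletion libraries with each other at 0.992. Deletion replicate 3 showed a much smaller excess in weakly expressed genes. At 1 to 2 RPKM its median was 1.88 RPKM, against 1.41 and 1.42 in deletion replicates 1 and 2. At 5 to 10 RPKM it was 8.21, against 6.98 and 7.31.

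**Figure D3:**
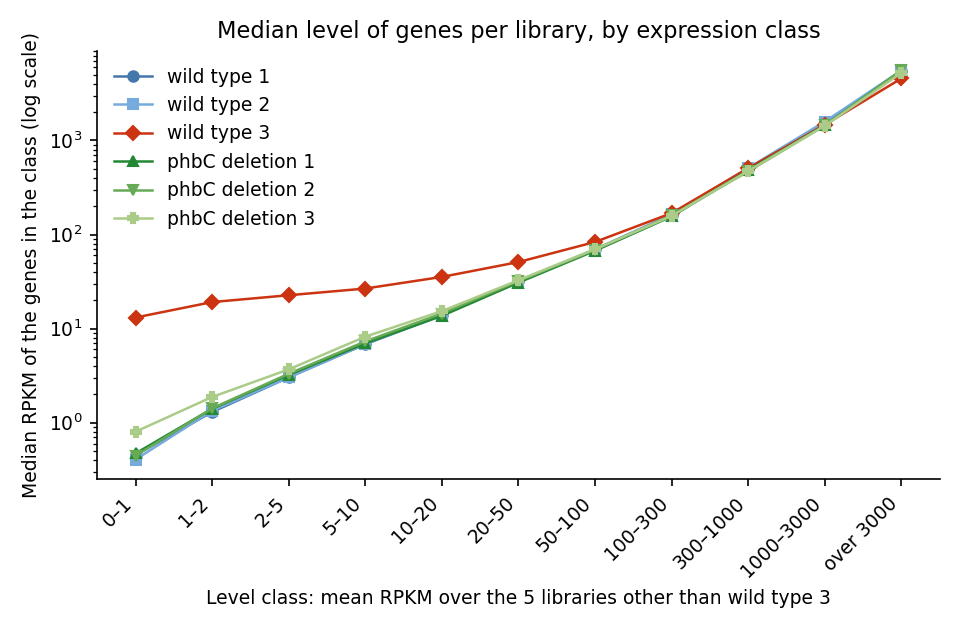
Median level of genes in each library, by class of expression. The horizontal axis gives classes of the mean RPKM over the 5 libraries other than wild-type replicate 3, the vertical axis gives the median RPKM of the genes of a class on a log scale, and each line is 1 library. Wild-type replicate 3 has a median of 19.1 RPKM in the class from 1 to 2 RPKM and of 508 RPKM in the class from 300 to 1000 RPKM, close to the other wild-type libraries. Over 3000 RPKM its median of 4574 RPKM is below those of the other 5 libraries.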

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

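With 212 genes in the reported fit, the deposited scale gave 609 (36.9% of them higher, against 59.4%), quantile normalization 643, a filter at 10 RPKM 321, a variance model without trend 73, and a minimum absolute log2 fold change of 1 gave 94. Chosen after seeing the data, array weights gave 1454, scaling on genes of at least 100 RPKM 561, removal of an even background from wild-type replicate 3 gave 563, and the deposited scale without that library 1131. Leaving out 1 library at a time gave between 60 and 1162 genes: 123, 113 and 1162 without wild-type replicates 1, 2 and 3, and 73, 60 and 64 without deletion replicates 1, 2 and 3. The genes shared with the reported 212 were 117, 112, 212, 73, 60 and 63, all in the same direction. The simulations with an addition to 1 library also lost calls of true changes; the cause in the real libraries was not tested. Without wild-type replicate 3, and also chosen after seeing the data, a minimum absolute log2 fold change of 1 gave 172. The replicate block gave 242 genes, 197 of them among the 212, voom on recovered reads (also chosen after seeing the data) 171, no filter 184, and pseudocounts of 0.1 and 10 gave 217 and 209. The block changed no call of a named gene. Alternatives for gene lists and for matching names, and the count-model tests, were not run. Atu0485, Atu0486 and Atu2708 passed the threshold in all 19 alternatives, with log2 fold changes of 5.36 to 5.80, 5.38 to 5.64 and -3.68 to -3.21. Atu1604 passed in 18, and missed it with the filter at 10 RPKM (adjusted p = 0.18, with a range of 3.8e-09 to 0.18), where its fold change was the same and its standard error rose from 0.51 to 1.81. Its fitted log2 fold change, from -8.93 to -1.56, depends on the pseudocount and is no bound. Atu1020 ranged from -0.27 to 0.12 when 1 library was left out, and Atu1131 from -0.13 to 0.39. Atu1131 was also at -0.0013 on the deposited scale, -0.16 with quantile normalization, -0.11 with array weights and -0.12 on the deposited scale without wild-type replicate 3, and neither gene passed the threshold in any setting. Atu3752 passed it once, on the deposited scale without wild-type replicate 3 (adjusted p = 0.039, with a range of 0.039 to 0.91). Depth limited genes near 1 read, worth 0.146 to 0.183 RPKM at the median length.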

Other observations

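The tests of blocks of numbers, of an even addition of reads, of a wrong label, of a removed gene, of too few reads and of shared transcription were chosen after the results were seen.

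Genes at 0 were spread unevenly over the identifier numbers. All 194 identifiers numbered 6000 to 6999 were at 0 in all 6 libraries, as were 364 of 541 (67.3%) numbered 5000 to 5999 and 169 of 872 (19.4%) numbered 4000 to 4999. The share was 18.8% for numbers 8000 to 8999, 7.5% for 3000 to 3999, 5.1% for those under 1000, 2.4% for 1000 to 1999 and 2.0% for 2000 to 2999.

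Calls were spread unevenly over the numbers. With 6 libraries, a smaller part of the genes numbered under 1000 rose than of the others (12 of 904, Fisher's exact test, adjusted p = 0.011), and likewise of those numbered 1000 to 1999 (13 of 923, adjusted p = 0.012). A larger part rose among those numbered 3000 to 3999 (37 of 882, adjusted p = 0.020) and 4000 to 4999 (29 of 689, adjusted p = 0.040). Without wild-type replicate 3 the same tests gave adjusted p of 0.052, 0.0022, 0.00037 and 0.66. Falls were fewer among genes numbered 1000 to 1999 (8 of 923, adjusted p = 0.024) and more among those numbered 4000 to 4999 (33 of 689, adjusted p = 9.0e-07), and without that library these tests gave 0.96 and 0.11. Fold changes of consecutive numbers were correlated, so these p-values, which take genes as independent, are too small.

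Genes with consecutive numbers changed together. Without wild-type replicate 3, the log2 fold changes of 3994 pairs of consecutive numbers correlated at r = 0.45, across genes. The correlation was 0.28 for numbers 2 apart, 0.08 for 5 apart and 0.02 for 10 apart. In 1000 shuffles among genes of like level the highest correlation was 0.07 (p = 0.001, the smallest these shuffles can give). The called genes formed 76 runs of at least 3 consecutive numbers in one direction, with 333 genes (28.7% of those called) and a longest run of 20, against at most 33 runs and a longest run of 8 in the shuffles. The background of wild-type replicate 3 is argued against, since that library was left out of the value of 0.45. Shared transcription of neighbouring genes stays open, since the correlation is the pattern itself and the positions of the genes were not used here. A read that overlaps 2 neighbouring genes directly links only those 2. The correlation of 0.28 over 3946 pairs of numbers 2 apart therefore argues against such reads as the only source. A part played by them stays open.

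Atu1604 was the 1 gene, among 4081 with at least 10 reads in every wild-type library, with 0 reads in every deletion library, and no gene showed the opposite. At the lowest wild-type level 624 reads would be expected over the 3 deletion libraries, which argues against too few reads as the reason. Its neighbours in number at distances of 1 to 3, 5 of which are listed, did not pass the test, with log2 fold changes from -0.45 to 0.26 (limma, lowest adjusted p = 0.58). Without wild-type replicate 3 these fold changes were between -0.09 and 0.07 (limma, lowest adjusted p = 0.48). Whether the gene was removed from the deletion strain stays open, since the count of 1 such gene is the observation itself and tests nothing further. Whether it is phbC stays open too, since the files pair the identifier with no name.

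Weakly expressed genes were higher in wild-type replicate 3. Over 1085 genes at 1 to 10 RPKM its median was 23.6 RPKM, against 3.83 in replicate 1. Replicate 1 thinned to the same depth gave 3.86. Thinning leaves the expected RPKM of a gene unchanged, because RPKM divides by depth, so this value was set in advance and tests nothing. A deletion culture labelled as wild type is argued against. Of 33 genes of at least 100 RPKM that differed strongly between the strains in the other 5 libraries, 100% lay nearer to the wild type. The median excess over replicates 1 and 2 was 12.7 RPKM in genes under 1 RPKM and 17.6, 19.3, 20.1, 21.1 and 19.1 RPKM in 5 classes from 1 to 50 RPKM. The highest was 1.66 times the lowest, so for weakly expressed genes the median excess depended little on the level. An addition of reads such as genomic DNA could give that, but class medians cannot show whether it was even between genes. The quartiles were 11.9 and 29.3 RPKM at 10 to 20 RPKM, and 3.79 and 23.0 RPKM under 1 RPKM. In that library 1 read was worth 0.183 RPKM at the median length, so the excess was uneven from gene to gene. No biological explanation was tested, since the labels give that culture no group of its own.

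Of the 929 genes at 0 in the other 5 libraries, 10 were above 0 in wild-type replicate 3. An even 16.4 RPKM would take 6.98% of its reads and leave the median of genes over 3000 RPKM at 0.933 of that of replicates 1 and 2, while the measured ratio was 0.822, so the addition does not account for all of the difference in the most abundant genes. At 1000 to 3000 RPKM the ratios were 0.941 and 0.946. Atu2109 took 3.34% of reads in that library, against 7.68% and 6.63% in replicates 1 and 2. In genes under 10 RPKM the median excess was 21.8, 15.3 and 21.3 RPKM for numbers under 1000, 1000 to 1999 and 2000 to 2999, and 20.3 and 16.9 for 3000 to 3999 and 4000 to 4999, and 15.7 and 8.99 for 5000 to 5999 and 8000 to 8999.

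The real division of the libraries by strain gave 212 genes in limma, and 1 of the 10 splits into 3 and 3, the real one, reached that number. The highest of the other 9 splits gave 0 (14 to 181 genes at an unadjusted p under 0.05, against 768, and 0 by voom), including the 3 others that part all 3 pairs of replicate numbers. Each of these 9 splits mixes the strains within a group. Real differences between the strains then widen the spread, so few calls could be foreseen there, and 0 is no null level for the 212. With 10 splits the share cannot fall under 0.05.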
